A study of Homo sapiens with 3 samples.

How the data were processed

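Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out in ALL-SIL, an established human cell line of T-cell acute lymphoblastic leukaemia (T-ALL). The 3 samples were an H3K4me1 ChIP, an H3K4me3 ChIP and the input DNA, with 1 library each, grouped by the sample titles. Cells were fixed with formaldehyde and chromatin was sheared by sonication, per the labels' protocols. Each mark was then pulled down with its own Abcam antibody (ab8895 for H3K4me1, ab8580 for H3K4me3) on protein A beads, per the labels' protocols.

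Peaks were called with MACS2 2.1.0.20150731 in broad mode with the human genome size setting, per the file headers. A q of 0.1 was set for broad regions and 0.05 for strong regions, and 1 read per position was kept, per the file headers. Each mark's library was set against the same input library and the larger library was scaled to the smaller, per the file headers. The expected background was the local one, from windows of 1000 and 10000 bp, per the file headers. Coordinates were in GRCh38, per the submitters' processing notes. The alignment paths named STAR, per the file headers, and its version and settings are not given in the sources used here. The deposited peak lists gave for each peak a pileup, which is a coverage signal of extended fragments averaged over the region. They also gave the fold enrichment over the local background, a ratio set by the authors' caller, and the −log10 of p and q, all deposited as means over each broad region. These scores were the authors' own and were used here to describe, rank or filter peaks within 1 list. Positions came from the caller's tables, which count from 1. The start in the deposited interval list was 1 bp lower for all 62087 H3K4me1 peaks and equal for all 11100 H3K4me3 peaks. The input library had no peak list of its own and entered only through the caller.

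Depth was read from the file headers. The H3K4me1 library held 37178510 tags, of which 34813455 were left after filtering. The H3K4me3 library held 32712237 tags, 30823016 after filtering, and the input 19953801 tags, 18859011 after filtering. The redundant rate was 0.06 in both ChIP libraries and 0.05 in the input, and the fragment length was modelled as 201 bp for H3K4me1 and 187 bp for H3K4me3. Peaks are positions called in 1 library, so there was no replicate error, no test between marks and no p-value. Shares carry exact (Clopper-Pearson) 95% intervals, which cover counting error only.

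The gene reference was the RefSeq annotation of GRCh38.p14, in the same build as the peaks, with 20037 protein-coding and 18303 lncRNA genes. It was used as gene spans without strand or transcripts. The design written before the data were examined placed peaks at transcription start sites of every transcript. Here a peak was instead placed at a gene boundary if it overlapped the window of 1 kb on each side of either end of a protein-coding or lncRNA gene. Other peaks were called gene body or intergenic. A start site inside a gene span, as at GATA3 or TCF7, is therefore missed, and a gene's 3′ end counts as a boundary. Marks were taken as overlapping from 1 bp. For the level at random positions, the peaks of 1 list were shuffled 100 times, each to a random position on its chromosome. The position lay in any 1-Mb bin that held a peak of either list, since no genome sequence was used to leave out unassembled stretches. A peak could leave its own bin, so local peak density was not kept. A flank held H3K4me1 if an H3K4me1 peak covered any base of the 2 kb beyond that edge of the H3K4me3 peak. Distal H3K4me1 peaks overlapped neither an H3K4me3 peak nor a boundary window, and were counted over each gene and 50 kb on each side. H3K4me1 peaks outside boundary windows of 2.5 kb were stitched across gaps of up to 12.5 kb. H3K4me3 peaks were merged into domains across gaps of up to 1 kb, and those of at least 4 kb were called broad.

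The 19 gene lists were fixed before the data were examined, as were the thresholds, windows and most alternatives. They were T-lineage genes, T-ALL transcription factor oncogenes, Notch target genes, T-ALL tumour suppressors, kinase and cytokine signalling genes, H3K4 methylation writers and erasers, housekeeping genes, DNA replication genes, markers of B-lineage, myeloid, erythroid and megakaryocyte, natural killer, liver, neuronal and muscle cells, and the HOXA, HOXB, HOXC and HOXD clusters. All 338 distinct genes were found in the annotation. Some genes stood in more than 1 list. Each list's share or median was given as a percentile among 10000 random lists of protein-coding genes of the same size, matched on gene length decile, as a description of these libraries. Every member was named where a list had 5 or fewer on the side described, and otherwise up to 6. Marked members were ranked by H3K4me3 length within 5 kb of a boundary, and unmarked ones by distal H3K4me1 peaks. Every T-ALL transcription factor oncogene was named, with the 15 protein-coding genes with the longest H3K4me3 domain at a boundary (longer domains inside a gene, as at EVL, are not among them) and the genes nearest the 10 largest stitched H3K4me1 regions. The 5 lncRNA genes with the longest domain and no protein-coding boundary within 5 kb, and the 5 peaks of highest fold in each list, completed the rule. Other genes are said to have been chosen after their values were seen, and single values of some list members are not reported here.

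The alternatives were peaks with a −log10 q of at least 10, the upper part of each list by −log10 q, equal numbers of peaks, other overlap rules, autosomes alone, other window, flank, distal, stitching and merging distances, another shuffle and unmatched random lists. Protein-coding boundaries alone, and peaks anywhere in a gene, were added after seeing the data. The background expected from the input was computed from the authors' pileup and fold as (pileup + 1) / fold − 1.

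Work was done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and overlaps were checked with bedtools 2.31.1. On simulated data, all 550 planted overlaps among 1101 peaks were found. Of 100 simulated random lists 3 fell outside the central 95% of their draws, and 95 of 100 lists with planted marks lay above it. On the real lists the overlap counts equalled those of bedtools, 5193 and 5951.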

Results

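H3K4me3, the histone mark of active promoters, and H3K4me1, which marks enhancers and the flanks of promoters, were mapped by ChIP-seq in ALL-SIL, a T-ALL cell line known to carry a TLX1 rearrangement and the NUP214-ABL1 fusion. The series describes itself as a map of H3K4me1 in this line. Each mark had 1 library, with 34813455 filtered tags for H3K4me1 and 30823016 for H3K4me3, and both were called against 1 input library with 18859011. The H3K4me1 list held 62087 peaks covering 111 Mb, and the H3K4me3 list 11100 peaks covering 17.6 Mb. H3K4me1 peaks had a median length of 1020 bp (quartiles 533 and 2007) and H3K4me3 peaks of 1397 bp (934 and 1967). The median fold over input was 2.37 for H3K4me1 and 4.53 for H3K4me3, and the median −log10 q was 2.27 and 8.97. With 1 library per mark no value has a replicate error, and intervals cover counting error only.

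The position of the marks relative to genes and to each other was compared. H3K4me3 lay at gene ends: 81.2% of its peaks (9017 of 11100, 95% interval 80.5 to 82.0) were at a gene boundary. On the main chromosomes, where peaks were shuffled, the share was 81.4% against 9.63% after shuffling, a ratio of 8.45. A further 1445 peaks lay in gene bodies and 638 (5.75%) between genes. Of H3K4me1 peaks, 56.5% (35101) were in gene bodies, 22.4% (13884) between genes and 21.1% (13102, 20.8 to 21.4) at a boundary. No shuffled share was computed for gene bodies, so a preference for them was not measured. The boundary share of H3K4me1 was 2.27 times the shuffled one of 9.30%. The marks met often: 46.8% of H3K4me3 peaks (5193, 45.9 to 47.7) overlapped an H3K4me1 peak, against 8.83% after shuffling, with 9.36% as the highest of 100 shuffles. From the other side, 9.58% of H3K4me1 peaks (5951, 9.35 to 9.82) overlapped H3K4me3, against 1.62%. Among H3K4me1 peaks this share was 31.1% at boundaries, 4.41% in gene bodies and 2.38% between genes. Distal peaks, away from boundaries and H3K4me3, made up 75.9% of the H3K4me1 list (47106). H3K4me3 peaks at boundaries were longer, with a median of 1484 bp, than those in gene bodies (984 bp) or between genes (695.5 bp). The overlap depended on how many weak peaks were kept and on the overlap rule: the H3K4me3 share was 1.86% among peaks with a −log10 q of at least 10, 26.6% in the upper part of each list, and 9.02% with as many H3K4me1 as H3K4me3 peaks. It was 11.4% when 50% of the peak had to be covered and 86.7% when a gap of 1 kb was allowed.

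At gene boundaries, which include 3′ ends, H3K4me1 lay more often beside the centre of H3K4me3 peaks than over it, and 45.4% of these H3K4me3 peaks (4092) overlapped an H3K4me1 peak. Of the 9017 H3K4me3 peaks at a gene boundary, 7.77% (701) had their midpoint inside an H3K4me1 peak, while 37.0% and 36.8% of positions 1 kb to the left and right were inside one. H3K4me1 was present within 2 kb on both sides of 58.3% of these peaks (5254, 57.2 to 59.3), on 1 side of 30.8% (2781) and on neither side of 10.9% (982). H3K4me3 peaks flanked on both sides had a median length of 1610.5 bp, those flanked on 1 side 1404 bp and those with no flank 1122.5 bp. At the 2067 H3K4me3 peaks away from boundaries on the main chromosomes, 28.9% of midpoints were inside H3K4me1. The share flanked on both sides was 1.14% among peaks with a −log10 q of at least 10, 23.6% in the upper part of each list and 6.85% with equal numbers of peaks.

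**Figure D1:**
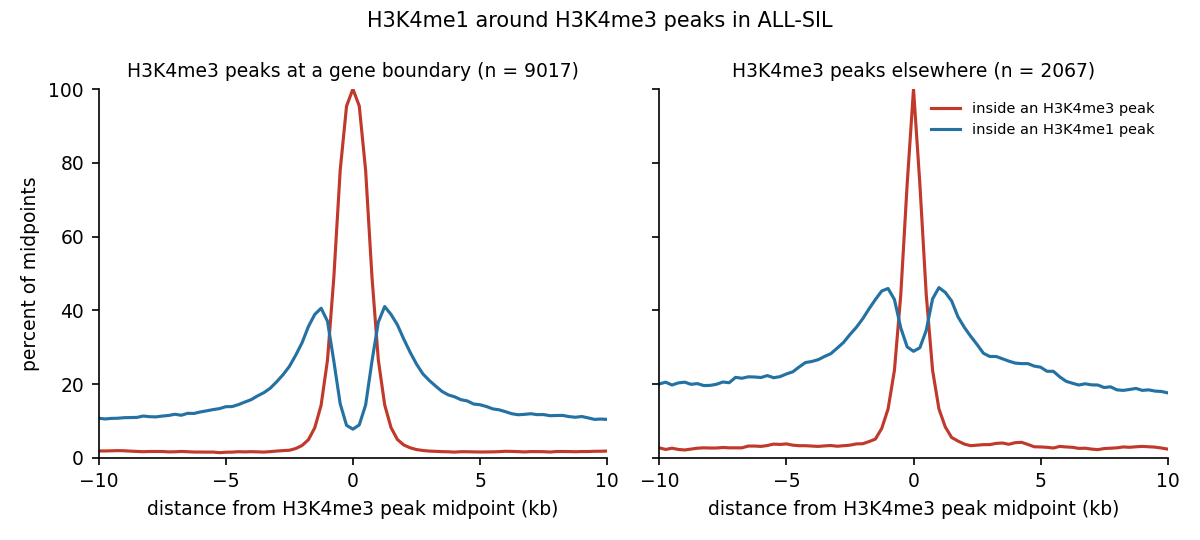
Percent of positions inside a called H3K4me3 peak (red) or H3K4me1 peak (blue) by distance in kb from the midpoint of H3K4me3 peaks, at gene boundaries (n = 9017) and elsewhere (n = 2067). H3K4me1 falls to 7.77% at the midpoint of boundary peaks and to 28.9% elsewhere, with shoulders of 37.0% and 36.8% at 1 kb on the left and right of boundary peaks.

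Of the 20037 protein-coding genes, 49.4% (9904) had H3K4me3 at a boundary and 42.6% (8532) had H3K4me1. Both marks were at 34.1% of genes (6827), H3K4me3 alone at 15.4% (3077), H3K4me1 alone at 8.51% (1705) and neither at 42.1% (8428). Genes with both marks, or with H3K4me3 alone, had a median of 4 distal H3K4me1 peaks within 50 kb, genes with H3K4me1 alone 5, and genes with neither mark 1. Among genes of at least 10 kb with H3K4me3 at a boundary, 96.6% (7492 of 7755) had it at exactly 1 of the ends. With peaks of a −log10 q of at least 10 the shares of genes fell to 22.3% for H3K4me3 and 1.55% for H3K4me1.

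T-lineage genes stood high for H3K4me1, as did some other lists. Of the 37 genes, 33 (89.2%, 74.6 to 97.0) had H3K4me1 at a boundary, above all 10000 random lists (percentile 100, random median 43.2%), and the exceptions were CD1D, DNTT, RAG1 and CD3G. Their median of 8 distal H3K4me1 peaks was also at percentile 100 (random median 3). H3K4me3 was at a boundary of 22 of them (59.5%, 42.1 to 75.2, percentile 79.4). Within 5 kb of a boundary, the most H3K4me3 was at LEF1, a nuclear effector of Wnt signalling, with 8.15 kb, at BCL11B, a factor of T cell commitment, with 7.44 kb, and at the T cell receptor chains CD3G (7.36 kb) and CD3D (7.16 kb). CD3D and CD3G shared 1 domain on chromosome 11 from 118338962 to 118346122 (GRCh38). TOX, a regulator of thymocyte development, had 4.64 kb. Of the 15 genes without H3K4me3 at a boundary, THEMIS had 20 distal H3K4me1 peaks, CD28 and CD8B had 12 and 11, and CD2, IL7R and CD5 had 10 each. Inside the gene, THEMIS held 7349 bp of H3K4me3, CD5 1670 bp and CD8B 917 bp, while CD28, CD2 and IL7R held 0 bp. Counting H3K4me3 anywhere in the gene, added after seeing the data, gave 28 of 37 genes (75.7%) at percentile 99.1. With peaks of a −log10 q of at least 10, or with equal numbers of peaks, the T-lineage median of distal H3K4me1 peaks was 0 (percentiles 50 and 49.5). The T-lineage H3K4me3 share at a boundary was at percentile 99.05 with that q limit and 96.3 in the upper part of the list. Kinase and cytokine signalling genes stood as high for H3K4me1 (91.7%, distal median 8, both percentile 100). Housekeeping genes had H3K4me1 at 80.0% (percentile 99.995).

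Most T-ALL transcription factor oncogenes, many of which are switched on in separate subtypes of the disease, were without H3K4me3. It was at 5 of 23 (21.7%, 7.46 to 43.7, percentile 0.62): TLX1, MYC, MYB, NOTCH1 and LYL1. TLX1, the homeobox gene rearranged in this line, lay in a domain of 13.1 kb on chromosome 10 from 101129245 to 101142355, at a fold of 3.99, and MYC in a domain of 6.37 kb. MYB had 3.70 kb, NOTCH1 3.22 kb and LYL1 a domain of 0.793 kb. TAL1, TAL2, LMO1, LMO2, LMO3, TLX3, HOXA9, HOXA10, HOXA11, NKX2-1, NKX2-2, NKX2-5, MEF2C, MYCN, SPI1, OLIG2, BHLHE22 and ZEB2 had none at a boundary. Of these, TLX3 and SPI1 had 4 distal H3K4me1 peaks each and TAL2 had 3, and LMO2 had H3K4me1 at a boundary. H3K4me1 was at 5 of the 23 oncogenes (percentile 1.6). Among the HOX clusters only HOXB fell below the range of most random lists, with H3K4me3 at 0 of 10 genes (interval 0 to 30.8, percentile 0.395). Genes of 1 cluster are neighbours and can share a peak, while random lists draw scattered genes. The cluster intervals and percentiles thus treat 1 locus as separate genes and overstate how far it stands apart. H3K4me3 was at 2 of 11 HOXA genes (among them HOXA4, percentile 11.4), 3 of 9 HOXC genes (percentile 20.3) and 1 of 9 HOXD genes (HOXD13, percentile 6.49). The HOXA, HOXC and HOXD shares were below the random medians but not below the range of most random lists. HOXC4, HOXC5 and HOXC6 shared 1 peak of 1.14 kb. H3K4me1 was at 1 HOXA, 0 HOXB, 4 HOXC and 2 HOXD genes.

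Signalling and growth control genes of T-ALL were mostly marked. Of 24 kinase and cytokine signalling genes 19 had H3K4me3 (79.2%, 57.8 to 92.9, percentile 99.5) and 22 had H3K4me1 (91.7%, percentile 100), with a median of 8 distal peaks (random median 3, percentile 100). The most H3K4me3 within 5 kb of a boundary was at the kinase PIM1 (6.06 kb), the apoptosis regulators BCL2 (5.46 kb), BCL2L1 (5.09 kb) and MCL1 (3.76 kb), the cytokine inhibitor SOCS1 (4.73 kb) and PIK3R1 (3.25 kb). PIK3CD, IL7R, JAK1, FLT3 and KIT had none at a boundary, with 13, 10, 9, 8 and 0 distal H3K4me1 peaks, and PIK3CD and JAK1 held 5045 and 1463 bp inside the gene. Of 26 tumour suppressors 23 had H3K4me3 (88.5%, 69.8 to 97.6, percentile 100) and 13 had H3K4me1 (percentile 82.0), with a median of 7 distal peaks (percentile 99.9). CDKN1B, a cell cycle inhibitor, had 12.8 kb of H3K4me3, WT1 6.99 kb and CNOT3 3.95 kb, beside LEF1 and BCL11B. The tumour suppressors without it at a boundary were GATA3, CDKN2A and CDKN2B, and GATA3 held 8867 bp of H3K4me3 inside the gene. Notch targets were close to random lists for H3K4me3, with 8 of 15 (53.3%, percentile 71.2). The marked ones were MYC, IGF1R (4.87 kb), TRIB2 (3.86 kb), NOTCH1, DTX1 (2.40 kb), HES1 (2.36 kb), HEY1 and NOTCH3. Among the unmarked, IL7R had 10 distal H3K4me1 peaks, the pre-T cell receptor chain PTCRA 5, HES5 and HEY2 4 each, HES4 2 and CR2 and NRARP 1 each. H3K4me1 was at 9 of the Notch targets (percentile 91.9), with a median of 4 distal peaks.

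Genes that dividing cells use widely were nearly all marked. All 30 housekeeping genes had H3K4me3 (interval 88.4 to 100, percentile 100), led by ENO1 (5.91 kb), YWHAZ (4.72 kb), EEF1A1 (4.61 kb), PGK1 (4.48 kb) and SDHA (4.23 kb), and 24 had H3K4me1 (80.0%). Of 27 DNA replication genes 26 had H3K4me3 (96.3%, percentile 100), with PCNA, the sliding clamp, at 5.89 kb, CDT1 at 5.67 kb and RRM2 at 4.67 kb. CDC45 had 3.47 kb, MCM7 3.30 kb and MCM4 3.12 kb, ORC1 was the exception with 2307 bp inside the gene, and 16 of the 27 had H3K4me1. Of 19 H3K4 methylation writers and erasers 17 had H3K4me3 (89.5%, percentile 99.9). The methyltransferases KMT2A, KMT2D and KMT2C had 5.38, 4.72 and 3.76 kb, and DPY30, WDR5 and KDM6A had 3.70, 3.57 and 3.55 kb. Of the DPY30 length, a domain of 2.67 kb lay beside the gene and was shared with MEMO1, and 680 bp lay inside DPY30. SETD1B and the germline gene PRDM9 had none at a boundary, but SETD1B held 10363 bp of H3K4me3 inside the gene, and H3K4me1 was at 8 of the 19 (percentile 46.5).

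Markers of other lineages had little H3K4me3, while H3K4me1 lay at 9 of 15 B-lineage markers. H3K4me3 was at 0 of 18 myeloid markers (interval 0 to 18.5, percentile 0.005), 0 of 15 erythroid and megakaryocyte markers (0 to 21.8, percentile 0.015) and 0 of 16 muscle markers (0 to 20.6, percentile 0.005). It was at 2 of 15 B-lineage markers (CD72 and CD79B, percentile 0.265), 2 of 15 natural killer and cytotoxic markers (NKG7 and EOMES, percentile 0.3), 2 of 16 liver markers (TAT and APOA1, percentile 0.175) and 2 of 16 neuronal markers (DLX1 and DLX2, percentile 0.095). H3K4me1 was at 9 of the 15 B-lineage markers (interval 32.3% to 83.7%, percentile 91.8) and 8 of the 15 natural killer markers (53.3%, percentile 76.0). It was at 5 myeloid, 3 erythroid, 3 neuronal, 2 liver and 2 muscle markers, with percentiles of 13.8, 7.94, 2.42, 0.395 and 0.835. The B cell kinase gene BLK had 10 distal H3K4me1 peaks, the B cell factor PAX5 8, VPREB1 6, and CD79A, FCER2 and IGLL1 5 each. The difference between lists was not tested.

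**Figure D2:**
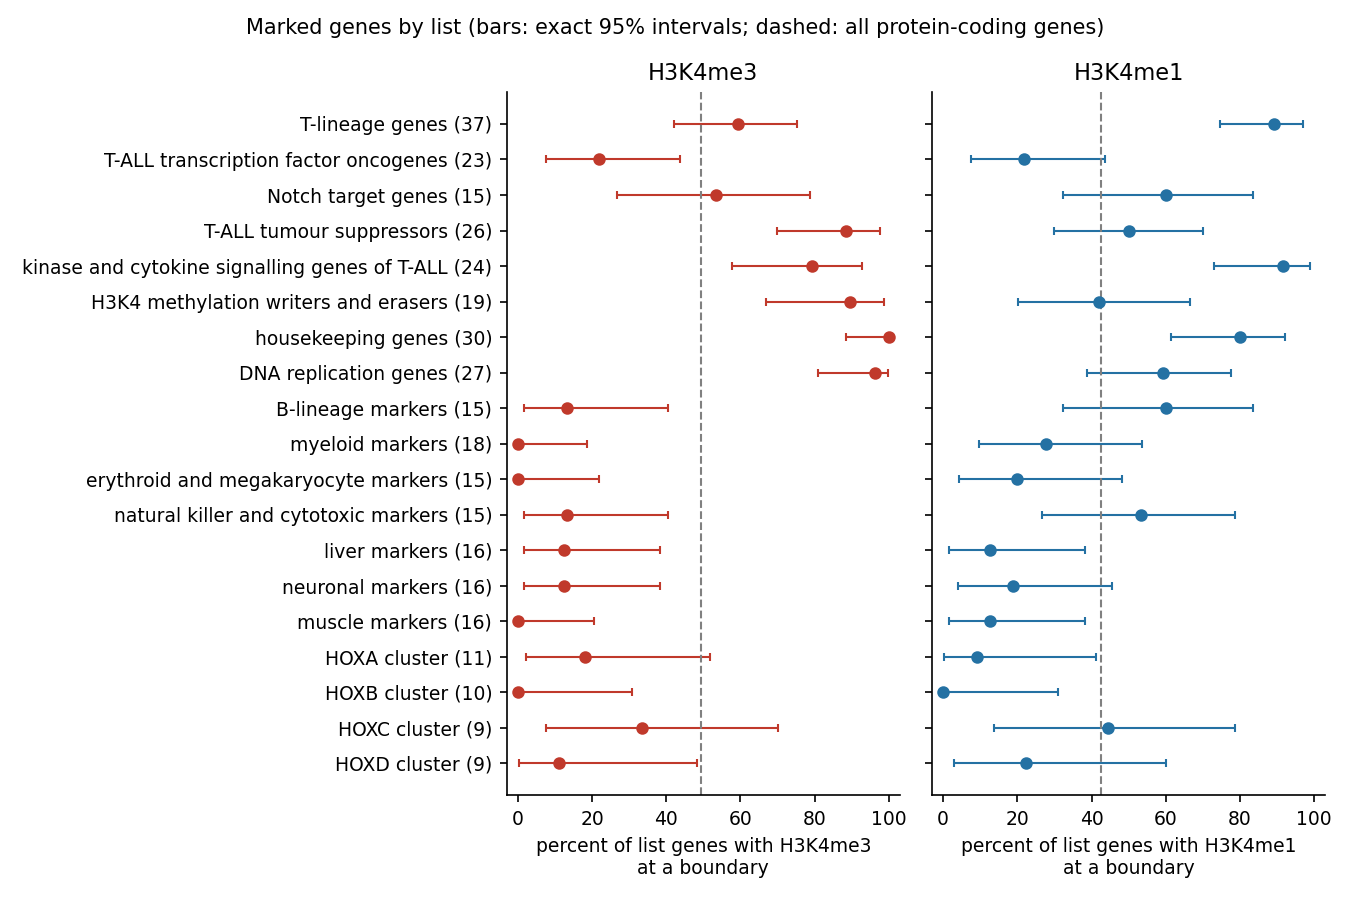
Percent of the genes of each list with a peak at a gene boundary, with list sizes in brackets and exact 95% intervals as bars, and the share of all protein-coding genes as a dashed line (49.4% for H3K4me3, 42.6% for H3K4me1). Housekeeping genes reach 100% for H3K4me3, myeloid, erythroid and muscle markers 0%, and T-lineage genes reach 89.2% for H3K4me1.

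The longest H3K4me3 domains at protein-coding genes included those of BCL11B, TLX1 and CDKN1B. Of 11036 domains 315 (2.85%) were at least 4 kb long, 250 of them at a protein-coding boundary, and 16 were at least 10 kb. MYO18B had the longest domain of a protein-coding gene, 17.9 kb on chromosome 22 from 25740354 to 25758261, and the phosphatase gene PTP4A2 came next with 16.1 kb (chromosome 1, 31923686 to 31939834). BCL11B had 13.7 kb (chromosome 14, 99260888 to 99274632, fold 5.56), of which 18.3% was covered by H3K4me1, and TLX1 had 13.1 kb with 0% covered. GPR19, CDKN1B and APOLD1 shared 12.8 kb on chromosome 12 from 12714432 to 12727213. The cohesin subunit RAD21 had 11.8 kb, KHDRBS1 11.3 kb, the cell cycle kinase CDK6 10.3 kb, the prostaglandin receptor PTGER4 10.3 kb, the chromatin remodeller ARID2 10.0 kb, PGGHG 9.88 kb and the interferon-induced IFITM1 9.85 kb. A domain of 11.3 kb beginning beside the end of TSPOAP1 lay over the lncRNA gene MIR142HG and the microRNA gene MIR142, which were named after their values were seen. Among lncRNA genes with a domain at their own boundary and no protein-coding boundary within 5 kb, TRG-AS1, in the T cell receptor gamma locus, had the longest domain, 23.8 kb on chromosome 7 from 38330486 to 38354262. GATA3-AS1 followed with a domain of 8.87 kb that began beyond its end and lay inside GATA3 (chromosome 10, 8053572 to 8062438). Then came MALAT1 with 8.84 kb, MIR181A1HG with 8.02 kb and LINC01089 with 7.38 kb. The LINC01089 domain also lay inside a protein-coding gene, SETD1B. The number of broad domains was 136 among peaks with a −log10 q of at least 10 and 182 in the upper part of the list.

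**Figure D3:**
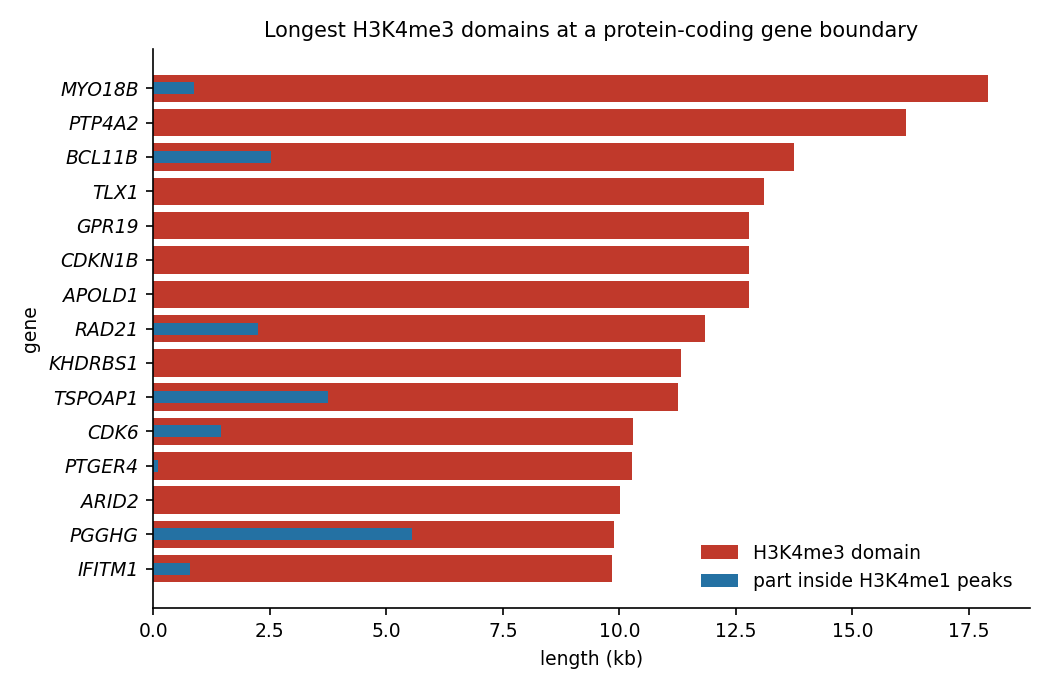
Length in kb of the merged H3K4me3 domain (red) and of its part inside H3K4me1 peaks (blue, summed from the left) at the 15 protein-coding genes with the longest ones at a gene boundary, where GPR19, CDKN1B and APOLD1 share 1 domain. MYO18B leads with 17.9 kb and IFITM1 closes the order with 9.85 kb.

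Stitched H3K4me1 regions covered long stretches of single genes. Of 19852 stitched regions 545 held at least 20 kb of H3K4me1. The largest lay over CHST11, with 233 kb covered in 289 kb (chromosome 12, 104462917 to 104752239), then HIVEP3 (228 kb covered in 306 kb) and the RNA-binding protein gene MSI2 (221 kb in 249 kb). A region on chromosome 6 from 21831209 to 22119793 lay over the lncRNA gene CASC15 with 175 kb covered, and its nearest protein-coding gene was LOC124901483, 165149 bp away. The kinase gene PRKCH and GALNT2 had 153 kb each, XYLT1 141 kb, UBASH3B 125 kb, CLEC16A 117 kb and the apoptosis regulator BCL2 109 kb. The count of such regions was 1 among peaks with a −log10 q of at least 10, 230 in the upper part of the list, 35 with equal numbers of peaks, 335 with a stitching gap of 5 kb and 1096 with boundary windows kept.

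The peaks of highest fold were short, but fold is a mean over each broad region, which can lower it in long ones. For H3K4me3 these were beside CAMK2D (fold 21.2, chromosome 4, 113762360 to 113762842), at DPP3 and BBS1 (17.0), at KREMEN2 (16.9), at the metallothionein gene MT2A (15.9) and inside PAX6 (15.7). For H3K4me1 the nearest genes were RIMBP3 (fold 12.49, 31803 bp away), ZNF322 (11.01, 59 bp away) and ZNF175 (10.9, 4184 bp away), and the others lay inside ZDHHC2 (10.7) and WWOX (10.4).

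**Figure D4:**
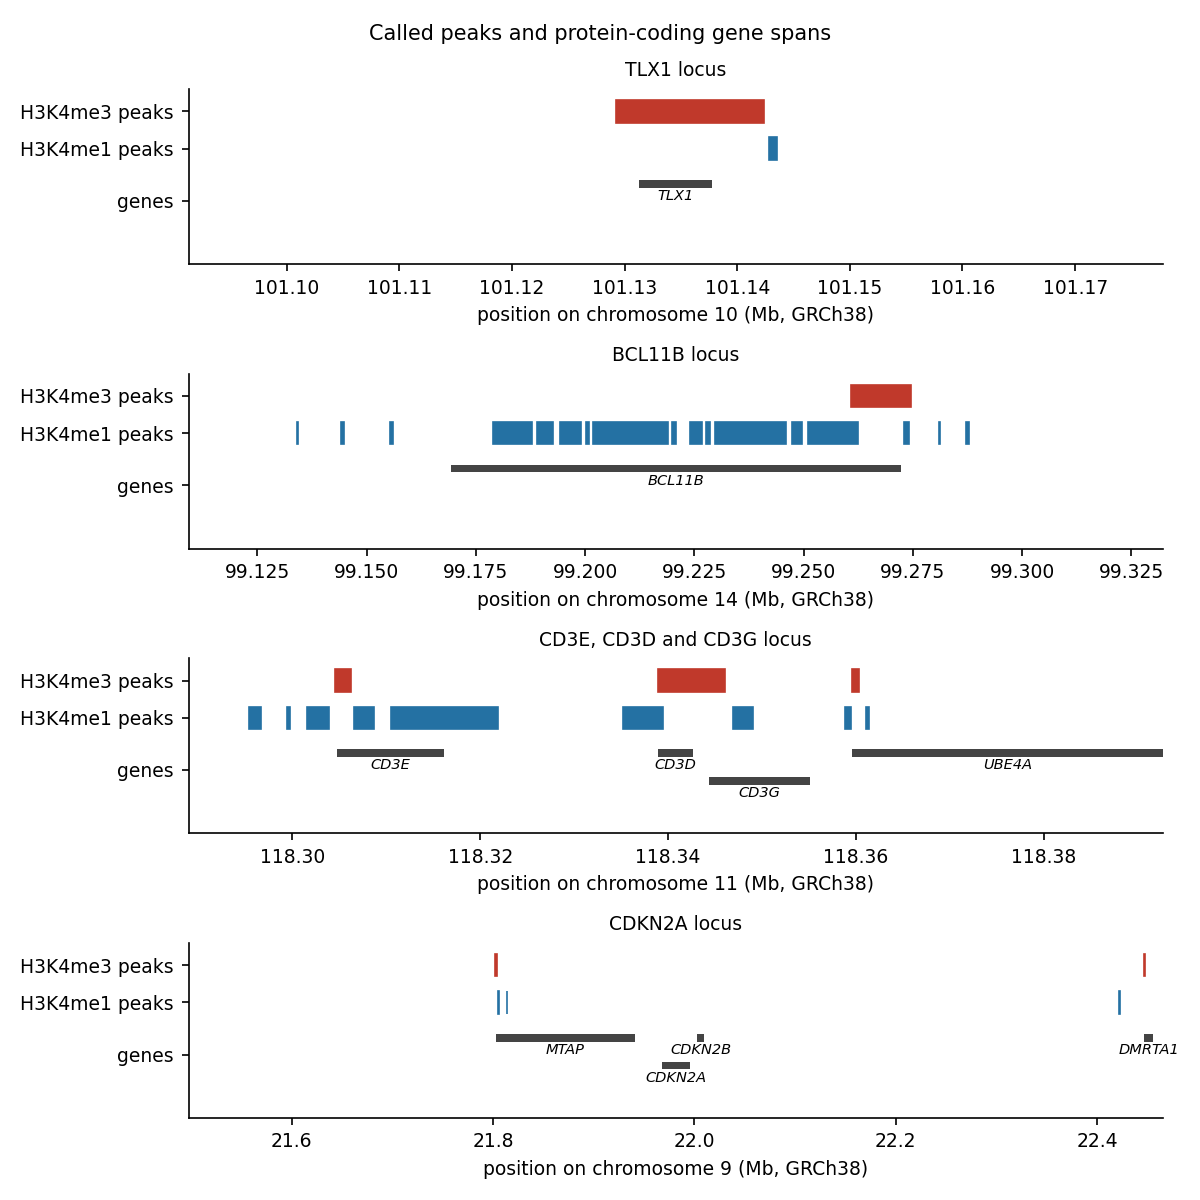
Called H3K4me3 peaks (red), H3K4me1 peaks (blue) and protein-coding gene spans (grey) by position in Mb (GRCh38) around TLX1, BCL11B, the CD3 genes and CDKN2A, with a thin outline that widens the narrowest peaks. The TLX1 domain spans 13.1 kb with H3K4me1 outside it, H3K4me1 covers much of BCL11B, and no peak lies over CDKN2A.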

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

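The tests on chromosome 8 were set out before their results were seen, once its higher background had been noticed, while the gene-level comparison of pileup and the comparison of folds were chosen after the first ratio was seen.

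The input library, which no comparison in the results uses by itself, gave a higher expected background at peaks on chromosome 8 than at peaks on the other autosomes. The median ratio was 1.33 for the H3K4me1 list (2.51 against 1.88, 3050 peaks on chromosome 8) and 1.36 for the H3K4me3 list (2.76 against 2.02, 396 peaks). A mixture of gene-dense bins was argued against, since the lowest ratio among groups of bins with like gene numbers was 1.30. A bias of the input alone would not raise ChIP pileup, whose upper quartile was at least 1.19 times higher too. A raised background lets only peaks of higher pileup be called, so that quartile cannot decide, and the fold ratios were 0.953 and 1.02. The gene-level value was the 90th percentile of pileup over all genes, with or without a peak, which the loss of weak peaks moves little. It was 11.6 on chromosome 8 against 9.55 on other autosomes for H3K4me1, and 23.4 against 18.6 for H3K4me3 (ratios 1.21 and 1.26). These values argue against a bias of the input alone at genes of high pileup, though their spread between chromosomes was not computed. More copies of chromosome 8 in these cells may account for the higher background, as its ratio was at least 1.19 on both sides of 45 Mb in both lists. The rise was uneven, with ratios of 1.39 (H3K4me1) and 1.46 (H3K4me3) above 45 Mb and lower ones below it. Copies of the whole chromosome and of a part of it were not told apart. Chromosomes 6 and 16 had H3K4me1 ratios of 1.186 and 1.179, and H3K4me3 ratios of 1.115 and 1.147. A base composition bias common to all 3 libraries was not tested, and chromosome 19, rich in genes, had ratios of 1.52 and 1.35. The study's groups give no biological contrast for the higher background on chromosome 8, and apart from copy number no biological explanation was tested.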

How the results depend on the processing

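Of the alternative values 65 moved by more than their counting interval or by over 1.5 times and 14 did not. Protein-coding boundaries alone, and peaks anywhere in the gene, were chosen only after the data were seen. With a −log10 q of at least 10, which keeps 1750 H3K4me1 and 4828 H3K4me3 peaks, 1.86% of H3K4me3 and 5.60% of H3K4me1 peaks overlapped the other mark, 21.7% of H3K4me1 peaks were at a boundary, 22.3% of genes had H3K4me3 and 1.55% H3K4me1, and 1.14% of boundary peaks were flanked on both sides. The median lengths were then 1427 bp (H3K4me3) and 849 bp (H3K4me1), 40.5% of T-lineage genes had H3K4me3 (percentile 99.0), their distal median was 0 (percentile 50), and 1 stitched region and 136 broad domains were left. In the upper part of each list by −log10 q the overlaps were 26.6% and 5.28%, the boundary shares 82.2% and 21.7%, the gene shares 25.7% and 23.9%, and the share flanked on both sides 23.6%. The lengths were 1445.5 and 1084 bp, the T-lineage share 40.5% (percentile 96.3), its distal median 4, and 230 stitched regions and 182 broad domains were left. With as many H3K4me1 as H3K4me3 peaks, 9.02% of H3K4me3 peaks overlapped, 9.09% of genes had H3K4me1, 6.85% of boundary peaks were flanked on both sides, the T-lineage distal median was 0 (percentile 49.5), 35 stitched regions were left and the H3K4me1 length was 949 bp. Fewer peaks enter these 3 settings by construction, which lowers the shares of genes and the counts. The distal percentiles of 50 and 49.5 come from ties, since nearly all random lists also had a median of 0 there.

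An overlap of 50% of the peak gave 11.4% and 1.09%, and a gap of up to 1 kb gave 86.7% and 23.3%. Autosomes alone gave 48.2% of H3K4me3 peaks. A shuffle over the whole chromosome gave ratios of 6.29 (H3K4me3) and 7.06 (H3K4me1), against 5.30 and 5.93. Boundary windows of 500 bp gave boundary shares of 79.6% and 14.2%, gene shares of 48.3% and 29.6% and a T-lineage percentile of 83.1, and windows of 2.5 kb gave 84.0%, 32.9%, 51.3%, 56.4% and percentile 72.2. Flanks of 1 kb and 5 kb gave 54.2% and 62.2% on both sides. The T-lineage distal median was 3 within 10 kb and 12 within 100 kb of the gene. A stitching gap of 5 kb gave 335 regions, and keeping boundary windows gave 1096. Random lists without length matching put the T-lineage H3K4me3 share at percentile 88.4. Protein-coding boundaries alone gave 75.4% and 15.5%. Peaks anywhere in the gene gave 53.4% of genes for H3K4me3, 63.4% for H3K4me1, and 75.7% of T-lineage genes at percentile 99.1. Beyond the effect of fewer peaks or other windows the cause was not tested.

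The number of broad domains was 300 without merging and 380 with a merging gap of 2 kb, and the T-lineage distal median was at percentile 100 in the upper part of the list, within 10 kb and 100 kb and without length matching. The 5′ end of the gene alone, start sites of every transcript and the exclusion of unassembled stretches were not run, since strand, transcripts and sequence were not used here. No paired analysis was possible because each mark had 1 library, and for the same reason no replicate could be left out. The effect of depth was not tested, since reads were not used here, and the median −log10 q was 2.27 for H3K4me1 and 8.97 for H3K4me3.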

Other observations

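The receptor loci, the broad domains by gene list and the tests on TLX1 and CDKN2A were chosen only after the result was seen.

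The T cell receptor loci carried long H3K4me3 domains and the immunoglobulin loci did not. The gamma locus (TRG) held 40.6 kb of H3K4me3 in 4 peaks, with a domain of 23.8 kb. The delta locus (TRD) held 20.7 kb, with a domain of 12.4 kb on chromosome 14 from 22449991 to 22462344. The alpha locus (TRA), which contains TRD, held 24.2 kb of H3K4me3 and 130 kb of H3K4me1, and the beta locus (TRB) 14.6 kb and 217 kb. The immunoglobulin heavy chain locus (IGH) held 3.48 kb of H3K4me3 in 3 peaks but 224 kb of H3K4me1 in 122 peaks, while the kappa locus (IGK) held 0.432 and 1.94 kb and the lambda locus (IGL) 2.04 and 24.1 kb. No domain of at least 4 kb lay in IGH, IGK or IGL.

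Broad H3K4me3 domains were at a boundary of 1.65% of protein-coding genes (330 of 20037). The counts by list follow the same rule, so broad domains inside a gene, as at GATA3, TCF7, THEMIS and SETD1B, are left out. They were at 7 of 37 T-lineage genes (18.9%, interval 7.96 to 35.2, percentile 100), among them CD247, LEF1, TOX, CD3D, CD3G and BCL11B. They were at 5 of 26 tumour suppressors (percentile 100), among them LEF1, WT1, CDKN1B and BCL11B, and PIM1, SOCS1, BCL2 and BCL2L1 made 4 of 24 kinase and cytokine signalling genes (percentile 100). ENO1, EEF1A1, YWHAZ and PGK1 made 4 of 30 housekeeping genes (percentile 99.9), MYC and TLX1 made 2 of 23 transcription factor oncogenes (percentile 96.7) and MYC and IGF1R 2 of 15 Notch targets (percentile 98.8). KMT2A and RRM2 were the only ones of their lists with a broad domain at a boundary (percentiles 85.0 and 77.6). The lists of other lineages and the HOX clusters had 0, as most random lists do (random median 0, percentiles 36.4 to 43.2).

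TLX1 lay in an H3K4me3 domain of 13.1 kb with no H3K4me1 peak inside, and the nearest H3K4me1 peak lay beyond its end, on chromosome 10 from 101142848 to 101143518. This was not particular to TLX1: the long domains of PTP4A2, CDKN1B, KHDRBS1 and ARID2 also had 0% covered, while those of MYO18B and BCL11B had 4.90% and 18.3%. The TLX1 peak had a −log10 q of 7.27, below the list median of 8.97. It is therefore absent from the settings with a −log10 q of at least 10 and with the upper part of each list. Extra copies of the locus stay open, as the background at the domain was 1.08 times the median of H3K4me3 peaks, but the central 90% of single peaks ran from 0.647 to 1.98 times. A domain shared with a neighbouring protein-coding gene was argued against by 0 others with a boundary there, while the lncRNA gene TLX1NB overlaps it. Long domains at homeobox genes in general stay open, since 0% of the 39 HOX genes had a broad domain but only 6 had H3K4me3 at a boundary, and the homeobox gene IRX5, named after its value was seen, had a domain of 5977 bp. The known rearrangement of TLX1 to a T cell receptor locus may underlie the domain, as a hypothesis that peak positions on the reference cannot test.

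No peak of either mark was called over CDKN2A and CDKN2B, in a gap of 608 kb on chromosome 9 from 21813846 to 22422236 that also takes in part of MTAP, whose H3K4me3 peak lies just outside. A deletion of the locus, frequent in T-ALL, may leave such a gap, but 21 of the 178 list genes without H3K4me3 lay in a wider one. A gene-poor stretch stays open too, since 25.3% of the gaps over 100 kb held as many protein-coding genes. These explanations cannot be told apart, as peak lists show no reads between peaks, and apart from a deletion no biological explanation was tested.

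Over the stretch from ABL1 to NUP214, both included, on chromosome 9 from 130713043 to 131234663, the background expected from the input was 0.836 times the autosomal median at 19 H3K4me1 peaks and 0.793 times at 3 H3K4me3 peaks. Peaks of chromosome 9 as a whole were also low, at 0.8997 (H3K4me1) and 0.8757 (H3K4me3) times the median of the other autosomes. The central 90% of single H3K4me3 peaks ran from 0.647 to 1.98 times their median, so the 3 H3K4me3 peaks do not stand apart. The copy number of this stretch was not tested.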
